A study of Mus musculus with 6 samples.

How the data were processed

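The series holds 6 poly(A)-selected RNA libraries of SB28, a mouse glioma cell line, 3 labelled PP2Ac knockout and 3 labelled wild type. The table the authors deposited gives raw read counts per gene symbol, 1 column per library and no pooled column. Per the submitters' processing notes, which name tools and builds without their roles, the software was fastp 0.20.0, STAR 2.7.1a, HTSeq 0.11.2, edgeR 3.34.0 and limma 3.48.3, with the builds mm10 and GRCm38. The annotation release and the strand setting of the counting are not given in the sources used here. Where exons of a gene lie over exons of a gene on the opposite strand, its reads and those of that partner therefore cannot be told apart, and reads shared by near-identical genes can be split or dropped. The deposited counts have no molecular identifiers, so counting intervals and floors cover counting error only.

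Each column was matched to its sample by the sample title, and 0 columns of other samples were present. Groups and replicate numbers came from the titles and the genotype label. The design text of the series speaks of SB28 tumours in wild-type hosts and in hosts with floxed PP2Ac and LysM-driven Cre, which deletes it in myeloid cells, whereas the sample labels give SB28 as the source and a PP2A genotype. Under the design text the knockout would lie in host cells, and under the sample labels in SB28. The labels do not settle which holds, or whether the RNA came from cultured cells or from tumour tissue, and the levels of tissue markers, given with the results, bear on the latter. Knockout and wild type are used here as the names of the labelled groups, and a fold change compares those groups of libraries, whichever cells carried the deletion. Nothing in the labels says how the knockout was made or whether the replicates were separate cultures. If they were not, the p-values measure only the spread between these libraries, which may be technical.

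The table lists 55453 symbols, of which 27491 had a count in any library. Library totals ranged from 38735864 to 49344079 counts. Genes were kept by filterByExpr of edgeR 4.0.16 with the group as design, which left 14877 genes holding 99.94% to 99.95% of each library's counts. Libraries were scaled by TMM, with factors from 0.967 to 1.035, and the groups were compared with the quasi-likelihood F-test of edgeR (glmQLFit and glmQLFTest, R 4.3.3). Benjamini-Hochberg adjustment ran over all tested genes, with a threshold of 0.05. The common biological coefficient of variation was 0.096. CPM values are counts scaled by library size and TMM factor, given as mean ± SD over n = 3 libraries. The standard error of a log2 fold change was taken from the fold change and its F statistic. For a gene with 1 to 3 counts in a group, the ratio of scaled counts is given with its 95% exact counting interval. For a gene with a count of 0 in a group, the bound is computed against a floor of 3 counts over the group.

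Before the data were examined, 33 gene lists were fixed, and so were the tests, the alternatives and the rule for named genes. The 31 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 31 lists. Camera asks whether a list moved relative to the other genes. Each list was tested again with a correlation estimated from the data and with fry, which asks whether its members move, on balance, one way. Only the sterol list passed the threshold with an estimated correlation. Some genes stand in more than 1 list. The genes of each chromosome were tested in the same way as the lists, adjusted over the autosomes and X. Positions came from GENCODE mouse release M21 on GRCm38, matched by symbol: 54402 symbols matched 1 gene, 108 matched several and 943 matched none. Exon overlaps between genes were taken from the same release.

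The named genes are Ppp2ca and Ppp2cb, whatever their values, and 12 genes of STING and interferon signalling, whatever their values. Added to these are the 8 highest and the 8 lowest fold changes among genes past the threshold that reached a mean of 5 CPM in a group, had no overlap between the groups and carried a gene name rather than a placeholder. From each list, up to 4 members with the smallest adjusted p could be named, within a limit of 40 genes besides the 12. A pair of genes that the rule selects is not reported here. Genes named outside this rule are marked as chosen after their values were seen.

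Replicates were compared before they were averaged. The chi-square statistic per degree of freedom between libraries of a group, over genes with a summed count of at least 20, was 41.81, 30.33 and 4.62 for wild-type pairs 1 and 2, 1 and 3, and 2 and 3. For the knockout pairs in the same order it was 49.38, 42.8 and 3.42. No pair lay within sampling noise, so no pair looked like the same library sequenced again, and all 6 libraries were kept. This check cannot tell separate cultures from separate preparations of the same RNA. The first principal component held 90.3% of the variance and separated the groups. The second held 4.5% and set both libraries numbered 1 (18.9 in wild type, 25.2 in knockout) apart from the other libraries (-14.4 to -8.6). Whether the numbers pair the libraries was checked by correlating, across genes, the deviations of each library from its group mean. Libraries with the same number correlated at 0.44, 0.16 and 0.15, each above the limit of 0.1. Deviations from a group mean cancel out within the group, so the match of the libraries numbered 1 makes the others correlate too. Wild type 3 correlated slightly better with knockout 2, at 0.19, than with knockout 3, and wild type 2 correlated with knockout 3 at 0.15. The data thus set number 1 apart but cannot pair numbers 2 and 3. Replicate pairs in this text are libraries that share a number, which is an assumption. The fit without the pairing stayed the main one, as fixed in the design, and the fit with the replicate number as a block is an alternative.

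The alternatives were DESeq2 size factors, upper-quartile factors, no filter, a filter of at least 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, the replicate block, a test against a fold change of 1.5 (glmTreat), and leaving out each library in turn. Chosen after seeing the data were leaving out both libraries numbered 1, leaving out the 200 most abundant genes, the gene families, and, for chromosomes, the replicate block. The calculations were tested on simulated data: counts for the 14877 genes were drawn from the real means and library sizes with 200 genes changed. The edgeR test recovered 22% of genes changed 1.25-fold, 68% of those changed 1.5-fold, 94% of those changed 2-fold and 98% of those changed 4-fold. Of 144 calls, 3 were unchanged genes. Camera called the list raised 1.5-fold and 0 of the unchanged lists. Genes were drawn independently, so this run could not show how often camera calls unchanged lists whose members are correlated.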

Results

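RNA abundance was measured by poly(A)-selected RNA sequencing in 6 libraries of SB28, a mouse glioma line with a C57BL/6 strain label. The labels give 3 libraries as knockout of PP2Ac, the catalytic subunit of protein phosphatase 2A, a major serine and threonine phosphatase, and 3 as wild type. Total counts were 49344079, 42937267 and 38735864 in wild type 1, 2 and 3, and 46149908, 42122935 and 40245915 in knockout 1, 2 and 3. The single comparison of the design sets knockout against wild type, and the series title ties it to STING and type I interferon signalling. Fold changes are knockout over wild type, and adjusted p values for genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested.

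Ppp2ca, the gene of the targeted subunit, was still abundant in the knockout libraries. It was present at 274, 244 and 247 CPM in wild type 1, 2 and 3 and at 217, 187 and 193 CPM in knockout 1, 2 and 3. The means were 255 ± 16.5 and 199 ± 15.6 CPM (SD, n = 3), a log2 fold change of -0.36 (SE 0.08, adjusted p = 0.00377), so the message was 1.28-fold lower. Ppp2ca (ENSMUSG00000020349.4) lies on chromosome 11, 52098681 to 52127778, plus strand, GRCm38, and the count sums reads over the whole gene. The labels do not say which part of the gene was altered, and a small change in the coding sequence, or a deletion in host cells as the design text of the series has it, need not lower the count, so the level is a weak check of the genotype label. Exons of a long noncoding RNA on the opposite strand cover 39.9% of its exon bases. Ppp2cb, which encodes the other catalytic subunit, rose from 85.9 ± 2.28 to 125 ± 2.04 CPM (log2 fold change 0.54, SE 0.06, adjusted p = 6.34e-05). Among 29 tested subunits and regulators of PP2A, 9 rose, 7 fell and 13 did not pass the threshold, both over all genes and adjusted over the list alone. Ppp2r5d, a regulatory subunit, fell from 129 ± 8.12 to 65.6 ± 3.95 CPM (log2 fold change -0.97, SE 0.08, adjusted p = 6.56e-06). As a list these genes did not differ from the other genes (camera adjusted p = 0.912).

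**Figure D1:**
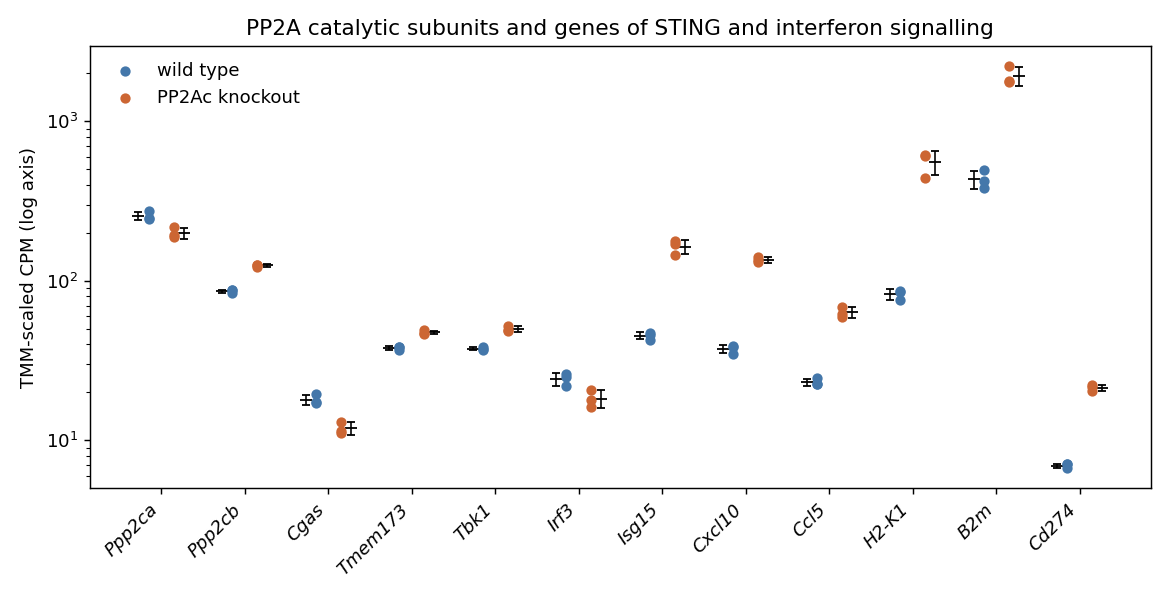
Levels of the 2 PP2A catalytic subunits and of genes of STING and interferon signalling in TMM-scaled CPM on a log axis, with each point 1 library (blue, wild type; orange, PP2Ac knockout) and mean ± SD over n = 3 beside it. Ppp2ca lies at 187 to 217 CPM in knockout and 244 to 274 CPM in wild type, while Isg15, Cxcl10, Ccl5, H2-K1, B2m and Cd274 are higher in every knockout library.

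The knockout and wild-type libraries differed in most expressed genes. Of 14877 genes tested, 9525 (64%) passed the threshold, 4752 higher and 4773 lower in the knockout. Of these, 1639 were at least 2-fold higher and 1591 at least 2-fold lower, and 648 and 558 at least 4-fold. The split of all calls moved with the scaling, so its near-even balance is not a result by itself. Upper-quartile factors gave 4298 higher and 5296 lower, and DESeq2 size factors 4832 and 4688. The groups did not overlap in 68.3% of the tested genes, where chance gives 10%. Both libraries numbered 1 stood apart from the other libraries of their groups. Without both libraries numbered 1 the test called 11123 genes, 9301 of them among the 9525. Against a fold change of 1.5, 3966 genes passed, 2009 higher and 1957 lower.

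The highest fold changes belonged to genes that were almost silent in wild type. Lcn2, which encodes the iron-siderophore binding protein lipocalin 2, rose from 0.0486 ± 0.0427 to 540 ± 25.3 CPM, and the collagenase gene Mmp13 from 0.0854 ± 0.0522 to 271 ± 43.2 CPM. C3, the central complement component, rose from 0.144 ± 0.0411 to 190.5 ± 9.32 CPM (log2 fold change 10.37, SE 0.14, adjusted p = 6.7e-10). Nos2, the inducible nitric oxide synthase, had 1 count in wild type against 2409 in knockout, a ratio of 2600 (95% counting interval 467 to 103000). The metalloreductase gene Steap4 had 1 against 3633 counts, a ratio of 3930 (705 to 155000). Ms4a4d had 0 counts in wild type and 752 in knockout, at least 271-fold higher. The receptor genes Lilrb4a and Lilr4b rose as well, the first with 2 against 3196 counts (ratio 1730, interval 478 to 14300) and the second from 0.0468 ± 0.028 to 69.1 ± 8.85 CPM. These neighbours on chromosome 10 are close paralogs and overlap a further annotated gene, which covers 35.3% of the Lilrb4a exon bases, so the split of reads between them is uncertain.

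Among the lowest fold changes, Dkk3, a secreted protein of the Dickkopf family, fell from 109 ± 3.89 to 0.154 ± 0.0365 CPM (log2 fold change -9.45, SE 0.13, adjusted p = 6.7e-10). The transcription factor gene Zfp521 had 989 counts in wild type against 1, a ratio of 915 (95% counting interval 164 to 36200). For the actin regulator Wasf3 the counts were 1364 against 2 (ratio 631, interval 174 to 5210), and for the homeobox gene Hdx 970 against 2 (ratio 449, interval 124 to 3710). Xist, the noncoding RNA that coats the inactive X chromosome (chromosome X, 103460366 to 103483254, minus strand, GRCm38), had 10097 counts in wild type and 26 in knockout. Its level was 74.5 ± 4.56 against 0.205 ± 0.0716 CPM (log2 fold change -8.46, SE 0.16, adjusted p = 2.32e-09), and exons of its antisense partner Tsix cover 11% of its exon bases. The cytokine receptor gene Il5ra fell from 13.1 ± 1.54 to 0.0629 ± 0.0573 CPM. Tnfsf11, which encodes RANK ligand, fell from 5.48 ± 0.538 to 0.0320 ± 0.0279 CPM.

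Interferon-stimulated genes were higher in the knockout, whereas the genes of the STING pathway upstream moved both ways and by less. Of 59 tested members of the type I interferon response list, 52 rose, 5 fell and 2 did not pass (the same counts adjusted over the list alone), with a median log2 fold change of 1.51. The list rose relative to the other genes (camera adjusted p = 8.92e-13), with adjusted p = 0.0657 with an estimated correlation. Zbp1, a sensor of Z-form nucleic acids, rose from 6.33 ± 0.173 to 121 ± 2.1 CPM. Isg15, a ubiquitin-like protein, rose 3.62-fold (log2 fold change 1.86, SE 0.09, adjusted p = 3.69e-07). Cgas, the cytosolic DNA sensor, fell by 0.60 on the log2 scale (SE 0.10, adjusted p = 0.000696). Tmem173, which encodes STING, rose from 37.9 ± 0.864 to 47.5 ± 1.2 CPM (log2 fold change 0.32, SE 0.07, adjusted p = 0.00222). The kinase gene Tbk1 rose by 0.41 on the log2 scale (SE 0.07, adjusted p = 0.000636), while Irf3, the transcription factor it phosphorylates, fell by 0.41 (SE 0.12, adjusted p = 0.0115). Cgas, Tmem173, Tbk1 and Irf3 did not pass the test against a fold change of 1.5. Ifnb1, the interferon beta gene, was too rare for the filter, with 1 count in wild type and 32 in knockout, a ratio of 34.6 (95% counting interval 5.78 to 1410). In the list of nucleic acid sensing genes, 19 of 30 rose, 10 fell and 1 did not pass, also adjusted over the list alone, and the list rose (median log2 fold change 0.56, camera adjusted p = 0.0115, adjusted p = 0.149 with an estimated correlation).

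Genes of antigen presentation by MHC class I rose, and so did chemokines and targets of NF-kB. In the MHC class I list 17 of 23 tested members rose, 1 fell and 5 did not pass, also adjusted over the list alone, with a median log2 fold change of 2.15 (camera adjusted p = 5.77e-06, adjusted p = 0.149 with an estimated correlation). B2m, the light chain, rose from 432 ± 56.1 to 1926 ± 253 CPM (log2 fold change 2.15, SE 0.12, adjusted p = 8.58e-07). Nlrc5, the transactivator of class I genes, rose from 27.3 ± 1.29 to 176 ± 1.41 CPM, and the heavy chain genes H2-K1 and H2-Q4 rose 6.72-fold and 43.9-fold, with reads that similar class I genes can share. Of 37 chemokines and cytokines 25 rose, 8 fell and 4 did not pass, also adjusted over the list alone (median log2 fold change 1.45, camera adjusted p = 7.8e-05, adjusted p = 0.132 with an estimated correlation). Ccl20 rose from 0.652 ± 0.0156 to 77.2 ± 1.56 CPM, Cxcl1 from 1.78 ± 0.19 to 167 ± 8.41 CPM, and Lif, a cytokine that signals through gp130, from 20.1 ± 1.32 to 1488 ± 96.4 CPM. The T cell attractants Cxcl10 and Ccl5 rose 3.62-fold and 2.73-fold. In the NF-kB list, to which Lcn2, Cxcl1 and Ccl2 belong, 22 of 26 rose, 2 fell and 2 did not pass, also adjusted over the list alone (median log2 fold change 1.44, camera adjusted p = 2.31e-07, adjusted p = 0.0657 with an estimated correlation). Ccl2, which attracts monocytes, rose 16.3-fold (log2 fold change 4.03, SE 0.08, adjusted p = 2.43e-09). Cd274, the checkpoint ligand PD-L1, rose from 6.96 ± 0.208 to 21.4 ± 0.976 CPM (log2 fold change 1.62, SE 0.09, adjusted p = 5.46e-07), with exons of an antisense RNA over 14.1% of its exon bases. Its list of immune ligands and checkpoints, 12 higher, 5 lower and 4 not past the threshold, did not pass as a list (camera adjusted p = 0.113), with the same counts adjusted over the list alone.

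**Figure D2:**
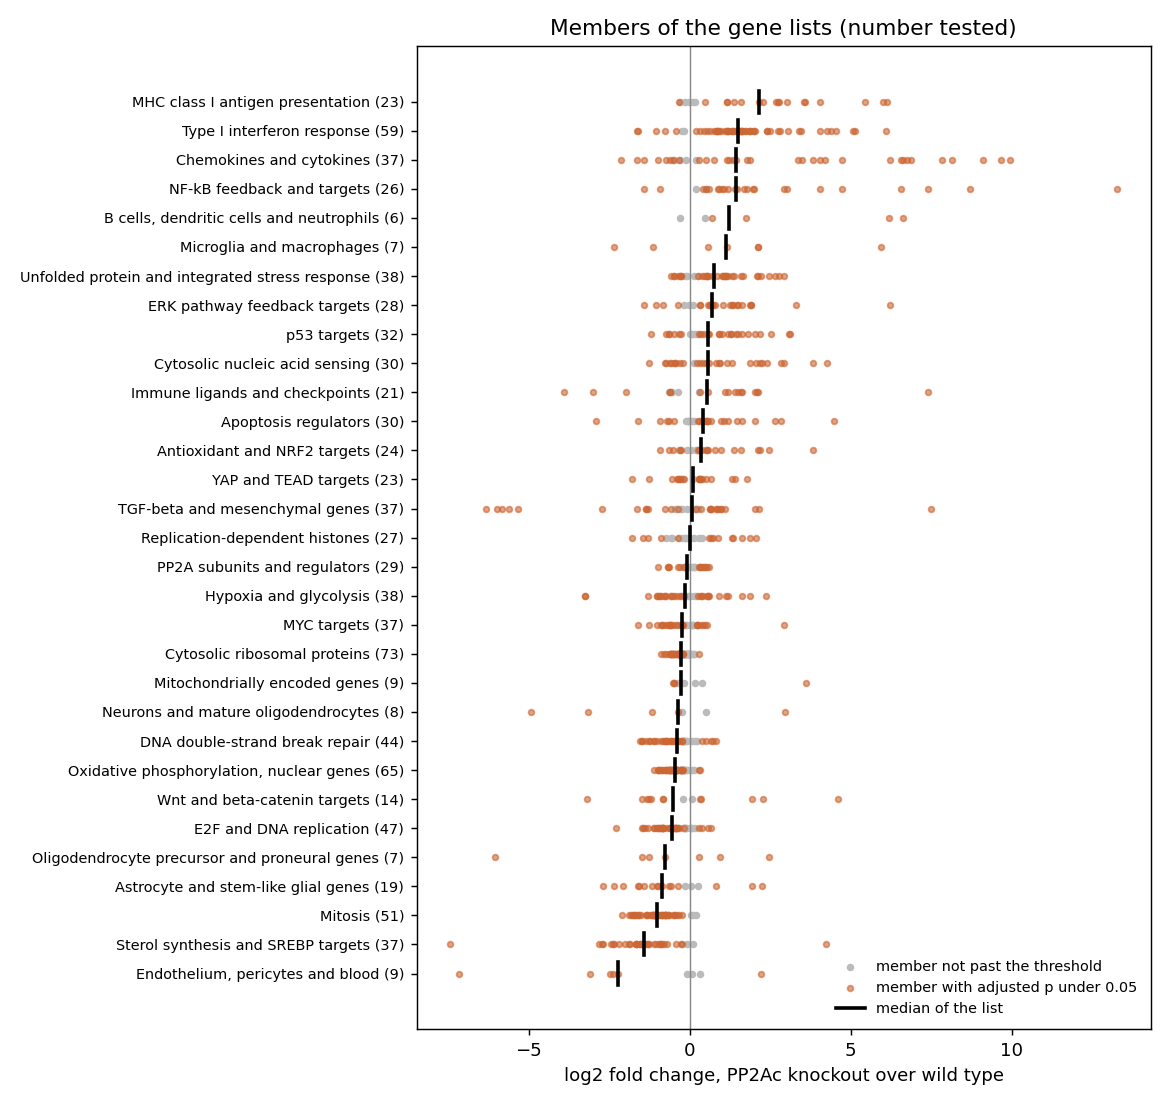
Log2 fold changes (knockout over wild type, horizontal axis) of the tested members of each gene list with at least 5 tested members, with the number tested in brackets. Points are genes, orange where the adjusted p is under 0.05 and grey otherwise, and black bars mark list medians, such as 2.15 for MHC class I and -1.43 for sterol synthesis.

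Genes of cell division were lower in the knockout. Of 51 tested mitosis genes 48 fell, 0 rose and 3 did not pass, also adjusted over the list alone, with a median log2 fold change of -1.01 (camera adjusted p = 1.4e-12, adjusted p = 0.149 with an estimated correlation). Aurkb, a kinase of chromosome segregation, fell from 52.8 ± 0.858 to 12.2 ± 0.63 CPM. In the list of E2F targets and DNA replication 34 of 47 fell, 4 rose and 9 did not pass, also adjusted over the list alone (median log2 fold change -0.54, camera adjusted p = 4.53e-06, adjusted p = 0.0819 with an estimated correlation), and the clamp loader gene Rfc5 fell from 47.2 ± 0.641 to 17.0 ± 0.0216 CPM. Among 44 genes of DNA double-strand break repair 26 fell, 5 rose and 13 did not pass, also adjusted over the list alone (median log2 fold change -0.38, camera adjusted p = 0.000651, adjusted p = 0.371 with an estimated correlation). Parp1, which encodes a poly(ADP-ribose) polymerase, fell from 169 ± 7.47 to 58.3 ± 4.57 CPM. Targets of p53 moved the other way, with 20 of 32 higher, 7 lower and 5 not past the threshold, also adjusted over the list alone (median log2 fold change 0.58, camera adjusted p = 0.00409, adjusted p = 0.132 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose from 34.6 ± 2.11 to 299 ± 13.5 CPM (log2 fold change 3.11, SE 0.08, adjusted p = 1.09e-08). MYC targets, with 8 higher, 20 lower and 9 not past the threshold, did not pass as a list (camera adjusted p = 0.12), nor did replication-dependent histones, with 9 higher, 5 lower and 13 not past it (camera adjusted p = 0.546), and the counts of both adjusted over the list alone were the same. The histone list holds messages without a poly(A) tail, at medians of 0.87 CPM in wild type and 1.16 CPM in knockout. Poly(A) selection largely misses such messages, so this list says little about histone expression.

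Genes of sterol and fatty acid synthesis fell almost without exception. Of 37 tested members 34 fell, 1 rose and 2 did not pass, also adjusted over the list alone, with a median log2 fold change of -1.43. The list fell relative to the other genes with the preset correlation (camera adjusted p = 2.23e-11) and passed with an estimated one too (adjusted p = 0.0374 with an estimated correlation). Sqle, the squalene epoxidase, fell from 311 ± 8.41 to 84.9 ± 1.92 CPM, and the desaturase gene Scd2 fell by 1.84 on the log2 scale (SE 0.06, adjusted p = 5.37e-08). The member that rose was Abcg1, a cholesterol exporter named here after its value was seen, from 0.111 ± 0.0431 to 2.14 ± 0.455 CPM. Nuclear genes of oxidative phosphorylation were lower in 49 of 65 cases, higher in 2 and not past the threshold in 14, with 51 lower and 2 higher adjusted over the list alone (median log2 fold change -0.47, camera adjusted p = 7.79e-07, adjusted p = 0.404 with an estimated correlation). Ndufb10, a subunit of complex I, fell from 44.4 ± 3.02 to 22.4 ± 1.72 CPM. Cytosolic ribosomal protein genes fell in 39 of 73 cases, rose in 1 and did not pass in 33, also adjusted over the list alone (median log2 fold change -0.26, camera adjusted p = 0.000446, adjusted p = 0.639 with an estimated correlation). Of 9 tested mitochondrially encoded genes 3 fell, 1 rose and 5 did not pass, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.521, median log2 fold change -0.26, mean 0.21). The tested members had medians of 2260 CPM in wild type and 1620 CPM in knockout, but mt-Co3 had only 14 and 22 counts. Also below the filter were mt-Nd3 (18 and 19), mt-Nd4l (4 and 4) and mt-Atp8 (1 and 1). The counts may therefore not measure these genes or mt-Co2, and why they were so low was not tested. For mt-Co2, the member that rose, knockout 1 held 329 of the 356 knockout counts. Its log2 fold change of 3.61 (adjusted p = 0.0332) was 0.61 without that library (adjusted p = 0.256), and it also lost the call without wild type 1 (0.0637), wild type 2 (0.0815) or wild type 3 (0.0805), with 0.256 the highest value over its alternatives. Of the 3 members that fell, 2 lost the call without wild type 1, knockout 2 or knockout 3.

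The lists of stress responses, ERK feedback, NRF2 targets and apoptosis were higher with the preset correlation and not with an estimated one. Those of hypoxia, YAP and Wnt targets passed with neither. The list of the unfolded protein and integrated stress responses had 27 of 38 members higher, 7 lower and 4 not past the threshold, also adjusted over the list alone (median log2 fold change 0.76, camera adjusted p = 6.69e-05, adjusted p = 0.149 with an estimated correlation). Atf3, a stress-induced transcription factor, rose from 12.3 ± 0.351 to 93.5 ± 5.25 CPM. Feedback targets of ERK signalling rose in 21 of 28 cases, fell in 4 and did not pass in 3, also adjusted over the list alone (median log2 fold change 0.69, camera adjusted p = 0.000211, adjusted p = 0.409 with an estimated correlation). Ier3, an immediate early gene, rose from 105 ± 6.39 to 1038 ± 113 CPM. For antioxidant genes and NRF2 targets 14 of 24 rose, 5 fell and 5 did not pass, with 14 higher and 6 lower adjusted over the list alone (median log2 fold change 0.34, camera adjusted p = 0.0154, adjusted p = 0.198 with an estimated correlation). Hmox1, the haem oxygenase, rose from 94.8 ± 4.84 to 1350 ± 55.7 CPM. Apoptosis regulators rose in 18 of 30 cases, fell in 6 and did not pass in 6, also adjusted over the list alone (median log2 fold change 0.42, camera adjusted p = 0.0453, adjusted p = 0.198 with an estimated correlation). With the replicate number as a block the apoptosis list did not pass (adjusted p = 0.0536), nor did it without wild type 3 (0.0539), without knockout 1 (0.0576) or without both libraries numbered 1 (0.056). Over all its alternatives the adjusted p ran from 7.26e-05 with fry to 0.198. Hypoxia and glycolysis genes (14 higher, 18 lower, 6 not past the threshold, camera adjusted p = 0.585), YAP and TEAD targets (10, 8 and 5, camera adjusted p = 0.823) and Wnt targets (5, 7 and 2, camera adjusted p = 0.565) did not pass camera as lists, with the same counts adjusted over the list alone. The Wnt list passed fry upward (fry adjusted p = 0.0457), while its camera direction was downward.

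Of the 4 members of the TGF-beta and mesenchymal list with the smallest p values, 3 fell and 1 rose. Acta2, smooth muscle actin, fell from 338 ± 11.4 to 6.84 ± 0.373 CPM, while Mmp3, the stromelysin, rose from 15.9 ± 1.98 to 2887 ± 117 CPM. The list had 15 of 37 members higher, 13 lower and 9 not past the threshold, with 16 and 13 adjusted over the list alone. It did not pass as a list (camera adjusted p = 0.823), and its measures differ in sign, with a median log2 fold change of 0.06, a mean of -0.53 and a downward camera and fry direction. Astrocyte and stem-like glial genes were lower in 13 of 19 cases, higher in 3 and not past the threshold in 3, also adjusted over the list alone (median log2 fold change -0.86, camera adjusted p = 0.0189, adjusted p = 0.304 with an estimated correlation). Of 7 tested oligodendrocyte precursor and proneural genes 3 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.585).

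Most markers of cell types other than glioma cells did not pass the filter on low counts. Of the markers in the table, 7 of 25 for microglia and macrophages, 1 of 23 for T and NK cells, 6 of 24 for B cells, dendritic cells and neutrophils, 9 of 21 for endothelium, pericytes and blood, and 8 of 20 for neurons and mature oligodendrocytes were tested. Over the 46 markers of microglia, macrophages, endothelium, pericytes and blood the median was 0.0196 to 0.0672 CPM per library, and 12 of them had 0 counts in all 6 libraries. The floor of 3 counts corresponds to 0.0587 to 0.0766 CPM. The tested microglia and macrophage markers were higher in 5 cases and lower in 2, also adjusted over the list alone, and did not pass as a list (camera adjusted p = 0.104). Leaving out any 1 wild-type library brought this list past the threshold, at 0.0379 without wild type 1, 0.0255 without wild type 2 and 0.0189 without wild type 3, and so did the filter of at least 1 CPM in 3 libraries (0.0233) and fry (3.01e-06), with 0.269 the highest value over its alternatives. Of the 6 markers of B cells, dendritic cells and neutrophils 4 rose and 2 did not pass, also adjusted over the list alone (median log2 fold change 1.22, camera adjusted p = 0.0295, adjusted p = 0.196 with an estimated correlation), and the list did not pass with the replicate number as a block (adjusted p = 0.0844), with voom weights (0.0646) or without both libraries numbered 1 (0.109), over a range of 9.85e-06 (fry) to 0.196. The single tested T and NK cell marker was higher. Endothelial, pericyte and blood markers had 1 of 9 higher, 5 lower and 3 not past the threshold, also adjusted over the list alone (camera adjusted p = 0.104). Ptprb, a phosphatase of endothelial cells, fell from 37.0 ± 0.816 to 0.260 ± 0.0903 CPM. Markers of neurons and mature oligodendrocytes had 1 of 8 higher, 4 lower and 3 not past the threshold, with 1 and 5 adjusted over the list alone (camera adjusted p = 0.216). Of the 5 sex-linked genes kept as a check of the labels, Xist alone was tested, and the 4 Y-linked genes had 0 counts in all 6 libraries.

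Genes of some chromosomes shifted together. Chromosome 10 was higher (713 genes, median log2 fold change 0.31, camera adjusted p = 0.000582, adjusted p = 0.0137 with an estimated correlation). Chromosome 13 was higher by a median of 0.35 over 601 genes (camera adjusted p = 0.000576, adjusted p = 0.6 with an estimated correlation), and chromosome 16 by 0.19 over 459 genes (camera adjusted p = 0.0373, adjusted p = 0.273 with an estimated correlation). Chromosome 6 (716 genes) and chromosome 15 (568 genes) were lower, each with a median log2 fold change of -0.22 and a camera adjusted p = 0.0373, with adjusted p = 0.189 and adjusted p = 0.6 with an estimated correlation. The call on chromosome 6 was lost without knockout 2 (adjusted p = 0.0629) or knockout 3 (0.0504), and that on chromosome 16 without wild type 2 (0.0563), with 0.0175 to 0.189 and 0.0261 to 0.273 over all alternatives of each. X-linked genes had a median log2 fold change of -0.17 and did not pass (camera adjusted p = 0.119), nor did the other 14 autosomes.

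**Figure D3:**
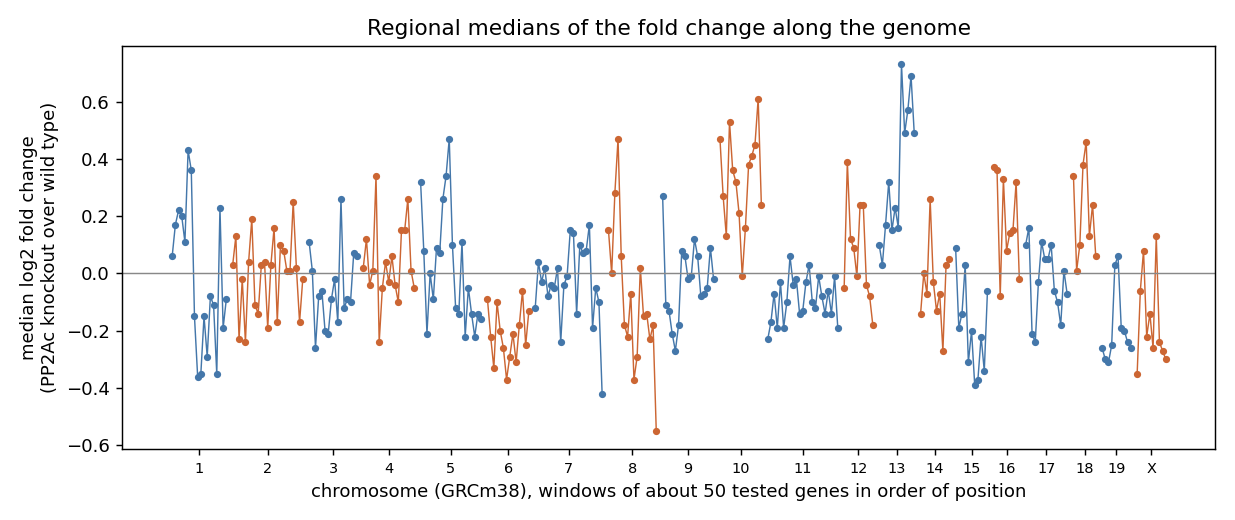
Median log2 fold change (knockout over wild type, vertical axis) of consecutive windows of about 50 tested genes in order of position along chromosomes 1 to 19 and X of GRCm38. Each point is a window and colours alternate between chromosomes; the windows of the distal part of chromosome 13 lie at 0.49 to 0.73.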

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

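Chosen only after the data were seen were the settings without both libraries numbered 1, without the 200 most abundant genes and, for chromosomes, the replicate block. Under the other settings run for the count of called genes, that count stayed between 8457 (without wild type 3) and 11495 (replicate block), but against a fold of 1.5 it was 3966, with 2009 higher and 1957 lower. Ppp2ca kept its log2 fold change of -0.36 there and lost its call (adjusted p = 1), since its fold lies under 1.5; under every other setting it stayed lower and past the threshold, at -0.42 to -0.30. DESeq2 shared 9049 of the 9525 calls, limma-voom 9449 and the replicate block 9510. The 146 other genes open to naming gave 2319 alternative values: 2286 kept direction and side of the threshold, 33 lost the call and 0 reversed. For the lists, 359 of 401 values kept both, 24 lost the call, 11 gained it and 7 reversed.

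With an estimated correlation, 0 lists were higher, 1 list was lower and 1 chromosome passed; chromosome 6 had an adjusted p of 0.189, chromosome 13 of 0.6, chromosome 15 of 0.6 and chromosome 16 of 0.273. Lists with strongly correlated members lose most in that test by its construction. With fry, which sets no list against other genes, 14 lists were higher and 12 lower. Of the lists that camera did not call, fry called immune ligands, Wnt targets and microglia higher. It called lower the mesenchymal list (fry adjusted p = 0.000135), MYC targets (0.0132), oligodendrocyte precursor genes (0.00287), and the endothelial and neuronal lists (1.71e-05 each). The PP2A list reversed direction without wild type 1 (0.998), knockout 2 (0.876) or knockout 3 (0.982), over a range of 0.824 to 0.998 with 1 library left out. The YAP list (0.309) and the Wnt list (0.0457) reversed with fry, and the mesenchymal list without both libraries numbered 1 (0.977). Leaving out 1 library gave 0.0422 to 0.0629 for chromosome 6 and 0.0393 to 0.0563 for chromosome 16. The cause of these reversals and lost calls was not tested.

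With the replicate number as a block, 11495 genes passed, the mesenchymal list reversed (adjusted p = 1), and the apoptosis and B cell, dendritic cell and neutrophil lists lost their calls, at 0.0536 and 0.0844. The B cell, dendritic cell and neutrophil list gave no value under the filter of at least 1 CPM in 3 libraries, which left it under 5 members. The block changed no other call among the named genes, lists and chromosomes. On simulated data of this depth, with 200 of 14877 genes changed, 68% of 1.5-fold and 94% of 2-fold changes were recovered, so small changes can be missed. With 64% of genes called in the real data the adjusted threshold is easier to pass, so these shares need not hold there.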

Other observations

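The tests of leukocyte transcripts and of tissue markers and the count of genes called in other splits were chosen after the result was seen, as were the gene families and the boundary on chromosome 13. Gene families by shared symbol stem were examined beyond the fixed lists. Of 410 families with at least 5 tested members, 9 passed camera with the preset correlation and 0 with an estimated correlation (adjusted p = 0.972 for each of the 9). Matrix metalloproteinases, which cleave extracellular matrix, were higher in 13 of 17 cases and lower in 3, with a median log2 fold change of 1.85 (adjusted p = 0.0274). The Klf transcription factors were higher in 11 of 14 and lower in 1 (median 0.71, adjusted p = 0.0274). The clustered protocadherins of the Pcdhb group, neighbouring genes of similar sequence whose reads can be shared, were higher in 8 of 10 and lower in 0 (median 2.02, adjusted p = 0.0274). Schlafen genes were higher in 6 of 7 (median 1.43, adjusted p = 0.0274) and guanylate-binding protein genes in 8 of 10 (median 1.98, adjusted p = 0.0373), both with 0 lower. Glutathione transferases of the Gstm group, again close paralogs, were lower in 6 of 6 (median -1.43, adjusted p = 0.0442). The Ifi (14 of 16 higher, 2 lower, median 2.08, adjusted p = 0.00327), Oas (6 of 6 higher, median 4.46, adjusted p = 0.00721) and Ccl families (9 of 11 higher, 2 lower, median 3.36, adjusted p = 0.0373) also passed. Of their members 8, 5 and 10 stand in the fixed lists, as do 3 of the matrix metalloproteinases, 3 of the guanylate-binding protein genes and 2 of the Gstm group.

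Xist was abundant in the wild-type libraries and near 0 in the knockout libraries. Reactivation of an inactive X would raise X-linked genes. The 480 X-linked genes other than Xist and genes that escape X inactivation lay below the autosomes instead. The difference in median log2 fold change was -0.17 (95% bootstrap interval -0.23 to -0.10), which argues against reactivation along the whole chromosome. The interval resamples genes and leaves out the spread between libraries. Chromosomes 6 and 15 had medians of -0.22, so a partial reactivation under such a shift stays open. Loss of the inactive X predicts lower levels of escape genes, yet their median lay above that of the other X-linked genes by 0.32, with a bootstrap interval of -0.51 to 0.54 over 9 genes, 3 of them higher and 3 lower (one-sided permutation p = 0.844). A difference at or above 0 had been set beforehand as counting against loss; the further demand that the interval exclude 0 was added after the value was seen, because the value does not exceed its spread, so loss of the inactive X may still be the cause. The genotype itself, and any difference between the cell populations that does not come from PP2Ac, stay open and were not tested.

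Among the 8 highest fold changes were 5 genes often read in myeloid cells, Lcn2, Nos2, Lilrb4a, Lilr4b and Ms4a4d, picked after their values were seen, while the fixed microglia and macrophage list, with 5 higher and 2 lower of 7 tested, did not pass (camera adjusted p = 0.104). As the source of these 5 genes, leukocytes would bring their abundant transcripts, but the median of Ptprc, Tyrobp, Fcer1g, Laptm5, Csf1r, C1qa, C1qb, Spi1, Cybb and Coro1a was 0.083 CPM in the knockout and 0.078 CPM in wild type, and Ptprc had 31 counts in wild type against 11 in knockout, which argues against them. Some markers went the other way, with Fcer1g at 16 counts in wild type and 37 in knockout, Cybb at 5 and 37, Lyz2 at 1 and 44 (ratio 47.6, 95% counting interval 8.1 to 1920) and Trem2 at 4 and 248, but their knockout levels were 0.292, 0.293, 0.357 and 1.99 CPM, where Lcn2 reached 540 CPM. Unsorted tumour tissue would bring the abundant transcripts of macrophages, endothelium and blood to both groups, but over all 46 members of those 2 fixed lists the median was 0.0196 to 0.0672 CPM per library, with 12 at 0 counts in all 6, which argues against such tissue as the source of the RNA. Expression by the SB28 cells themselves, cultured or purified, is a candidate explanation for these 5 genes that stays open as a hypothesis, and no test here ties it to PP2Ac.

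Of the tested genes 64% passed the threshold, 9525 in the labelled split. The highest of the other splits of the 6 libraries gave 0 with edgeR, the tool run on the splits. Each other split mixes the labelled groups, so their difference adds to the spread within its groups and holds its count down. The counts of the other splits therefore do not show what chance alone would give. At an unadjusted p under 0.05 the labelled split had 10031 genes, and the others of the 4 splits that part all 3 replicate pairs at most 24. The 6 splits that part only 1 replicate pair had 20 to 183. Only the labelled split of the 10 reached its own count, and 10 splits are too few for a share under 0.05. In the fit without the 200 most abundant genes 64% of genes passed as well, so the share of calls did not rest on including those genes. TMM already trims the most abundant genes when it sets the scale, so this fit could not decide whether abundant genes moved it. Copy number differences shared by neighbouring genes are argued against as the cause of most calls beyond 1.5-fold. After the median of the 50 nearest genes was subtracted, the count of called genes beyond 1.5-fold was 95.9% of that before (5548 against 5787). Of the same genes 4968 (85.8%) stayed beyond it in the same direction, and 580 were beyond it only after. Calls under 1.5-fold were not examined in this way, so for them the question stays open. Window medians varied more (SD 0.212) than in 100 shuffles of positions (at most 0.134), and segments smaller than the window and the genotype itself stay open, untested.

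For the gene lists, only the labelled split of the 10 reached its count of 18. The highest of the others called 14 (12 among those that part all 3 replicate pairs). For chromosomes, only the labelled split reached its count of 5, and the highest of the others called 3 (2 among those that part all 3 replicate pairs). Each other split still sets 2 libraries of one group and 1 of the other against the reverse, so it keeps part of the labelled difference, and 10 splits are too few for a share under 0.05.

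On chromosome 13, the 251 tested genes from position 64133018 to 119790889 had a median log2 fold change of 0.61 (quartiles 0.11 and 1.01), with 78.9% above 0. The 350 genes before that position had a median of 0.19 (quartiles -0.35 and 0.62). Chromosome 10 had a median of 0.31 with 68% of genes above 0, and the chromosomes other than 10 and 13 a median of -0.04 with 47.7% above 0. No explanation was tested for this boundary.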
